A study of Homo sapiens with 21 samples.

How the data were processed

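RNA was measured in SH-SY5Y neuroblastoma cells that had been differentiated for 11 days and exposed for 24 h to 30 µM of 8:2 FTOH, 8:2 FTS, PFDS, PFDA, PFOS or PFOA, with 1% methanol in the final treatment solutions, or kept as controls. The sources used here do not state the methanol content of the controls. Each of the 7 groups has 3 libraries, 21 in all. Nothing in the sample descriptions says that the 3 libraries of a group come from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

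Per the submitters' processing notes, the authors checked reads with FastQC and MultiQC, aligned them with HISAT2 to hg38, sorted them with SAMtools and counted them per gene with featureCounts. Per the file headers, featureCounts was version 2.0.1, run without strand or read pair options, and reads that mapped to several places or overlapped several genes were not counted. The library kit was stranded, so a gene that overlaps another on either strand may share or lose reads. The deposited raw table holds counts for 62656 genes in 21 libraries, 99.97% of them with a symbol entry. The authors' normalized table holds values in the unit signal for 37476 genes in 19 libraries, without control replicate 3 and 8:2 FTOH replicate 3. These values were raw counts divided by 1 factor per library: multiplied back, 100% were whole reads within 0.01 and 100% of those equalled the raw counts. The raw counts were used for every test.

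Total counts per library ran from 7680024 to 30429746 (median 14633793), and 30953 to 36740 genes had a count. Genes were filtered with filterByExpr of edgeR 4.0.16, which left 24879, and scaled with TMM. A quasi-likelihood model with robust dispersion was fitted over all 21 libraries in R 4.3.3, with a biological coefficient of variation of 0.1124, and p-values were adjusted over genes by Benjamini-Hochberg within each of 14 comparisons at 0.05. The comparisons were each of the 6 compounds against control, PFDA against PFOA and PFDS against PFOS for chain length, the difference between those, PFOS against PFOA and PFDS against PFDA for head group, and 8:2 FTS against 8:2 FTOH, PFOS and PFDS. All were written down before the data were examined, as were 32 gene lists and the alternatives, except where the text says otherwise. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, which compares a list with other genes, adjusted over the 192 tests against control and over the 256 others, and again with an estimated correlation and with fry.

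Genes named for a compound against control were the 8 largest rises and the 8 largest falls among protein-coding genes past an adjusted p of 0.05 with a mean of at least 1 CPM in the higher group and no overlap of the 3 treated and the 3 control libraries, and up to 4 members of each list with the smallest adjusted p. Between compounds 5 and 5 were taken. Genes outside this rule are marked as named after their values were seen. Counting ignored strand, so values of genes that overlap another expressed gene are uncertain. Overlaps with a named partner are stated beside some values. GAP43, MAP1B, DBH, NEFM, STIP1, PDIA3, ALDOA, SLC2A1, HSPA8, HSP90AA1, ARSJ, IDI1, CDH11, CDH20, TBX3, U3, ME1, TXNRD1, SHMT2, ENSG00000290960 and ENSG00000279602 overlap another expressed gene too. Single values of a few genes that the rule selects are not reported here, while the counts of genes and the list tests include them.

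The alternatives were DESeq2 size factors in edgeR, scaling by library size only, no filter on low counts, a stricter filter (mean CPM of 1 and 10 counts), the DESeq2 1.42.0 test, a fit of only the groups compared, a term for the replicate number, a minimum fold of 2, and leaving out each library in turn. Leaving out the 2 libraries that are absent from the authors' normalized table, and comparing the 6 compound groups together with control, were chosen after seeing the data. Trends with GC content and gene length were removed with a lowess span of 0.3, and 94.42% of tested genes had a GC value. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

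The procedure was tested on simulated data with the depths and spread of these libraries, in which changes were planted for PFOA. Of 50 planted genes each at 1.5, 2, 3 and 4-fold, edgeR recovered 23, 36, 45 and 50 and DESeq2 26, 38, 47 and 50, with median fitted folds of 1.49, 2.01, 3.05 and 3.99 for edgeR. Among unchanged genes edgeR made 6 false calls and DESeq2 16, and in 10 comparisons without planted changes edgeR made at most 2. Every gene was drawn with 1 spread for all libraries, so no simulated library stood apart from its group. Real libraries may be less even, so these numbers give no rate of false calls for them. A list planted at 1.25-fold passed with the preset correlation (adjusted p = 5.57e-30), with the estimated correlation (6.63e-06) and with fry (1.31e-06). Of 320 other list tests 0 passed with the preset or the estimated correlation, and fry was not counted there. Genes were drawn independently of each other. The simulation therefore does not show how often the preset correlation gives false list calls where genes correlate. Whether libraries of a group were copies of each other was checked over 21 pairs within groups, whose counts differed by more than sampling error (chi-squared per degree of freedom from 3.78 to 39.3).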

Results

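SH-SY5Y is a human neuroblastoma line that can be differentiated into neuron-like cells. The cells had been differentiated for 11 days and then exposed for 24 h to 30 µM of 1 of 6 per- and polyfluoroalkyl substances (PFAS), a level the series describes as sub-toxic, to study neurotoxic effects of these compounds. PFOA and PFDA are perfluoroalkyl carboxylic acids with a shorter and a longer chain, PFOS and PFDS are the corresponding sulfonic acids, 8:2 FTS is a fluorotelomer sulfonic acid and 8:2 FTOH is a fluorotelomer alcohol. Ribosome-depleted total RNA was sequenced from 3 libraries per compound and 3 control libraries, 21 in all, and reads were counted per gene. The total count per library ran from 7680024 (8:2 FTOH replicate 3) to 30429746 (PFOS replicate 1), with a median of 14633793. All 3 control libraries lay above that median, at 22179910 to 24905803, while every compound group had at least 1 library below it. Depth thus differed in part between control and compounds, and its effect was not tested. Levels are given in CPM, counts relative to the TMM-scaled size of the library, as mean ± SD over 3 libraries, and coordinates are on build hg38.

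Transcripts of neuronal genes were abundant in the control libraries. No undifferentiated cells were measured, so these levels do not show how far the cells had differentiated. MAP1B, which encodes a microtubule-associated protein of growing axons, was at 5404 CPM ± 104, GAP43, a growth cone protein, at 300 ± 5.76, the medium neurofilament gene NEFM at 186 ± 11.8, and DBH, which encodes the enzyme that makes noradrenaline, at 1146 ± 78.9. MKI67, a marker of cycling cells, was also expressed, at 856 CPM ± 32.2. A pair of libraries stood apart from the rest: mitochondrially encoded genes took 6.33% of the counts in control replicate 3 and 6.11% in 8:2 FTOH replicate 3. PFDA replicate 2 and PFDS replicate 1 were at 5.4% and 5.24%, and the other 17 libraries lay between 3.37% and 4.37%. This share counts all genes of the mitochondrial chromosome, not only those that encode proteins. Control replicate 3 and 8:2 FTOH replicate 3 are also absent from the authors' normalized table, which holds 19 libraries.

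**Figure D1:**
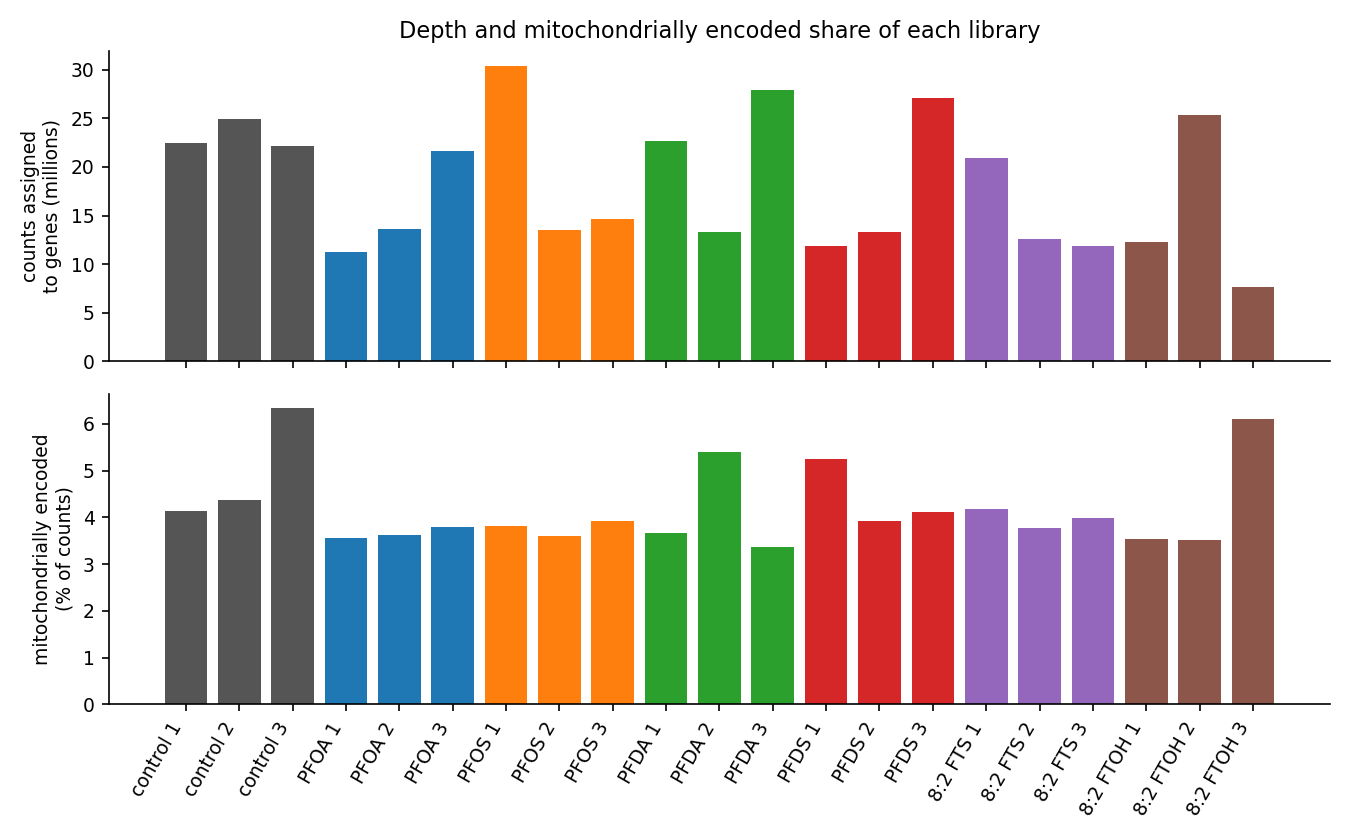
Counts assigned to genes (top) and the percentage of counts in mitochondrially encoded genes (bottom), with 1 bar per library, coloured by treatment. Control replicate 3 (6.33%) and 8:2 FTOH replicate 3 (6.11%) have the highest mitochondrial shares, and 8:2 FTOH replicate 3 is the shallowest library at 7680024 counts.

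Each compound was first compared with control, over 24879 genes. Lower expression of the immediate early genes EGR1 and FOS, which encode transcription factors induced by growth factors and neuronal activity, was the most frequent call: each fell for 5 of the 6 compounds. The cystine transporter gene SLC7A11 rose for PFOS, 8:2 FTS and 8:2 FTOH. In all, 38 different genes passed for at least 1 compound, 33 of them for 1 compound only. The calls were few: 8 genes for PFOA, 6 for PFOS, 2 for PFDA, 6 for PFDS, 21 for 8:2 FTS and 8 for 8:2 FTOH. The precision behind these counts was similar for all 6 compounds, with a median distance of 0.29 to 0.30 on the log2 scale from the estimate to the bound of its 95% interval among genes at 1 CPM or more. Between 86.02% and 87.81% of those genes had an interval that lay within a 2-fold change either way. The balance of rises and falls depended on control replicate 3 and on the scaling. Without control replicate 3 alone, higher and lower genes were 63 and 76 for PFOA, 17 and 7 for PFOS, 9 and 12 for PFDA, 14 and 9 for PFDS, 20 and 24 for 8:2 FTS and 14 and 18 for 8:2 FTOH. Counts under library size scaling are given with each compound. When control replicate 3 and 8:2 FTOH replicate 3 were both left out, an alternative chosen after seeing the data, 174 genes passed for PFOA (89 higher, 85 lower), 33 for PFOS (26 and 7), 24 for PFDA (11 and 13), 28 for PFDS (19 and 9), 60 for 8:2 FTS (30 and 30) and 11 for 8:2 FTOH (6 and 5).

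**Figure D2:**
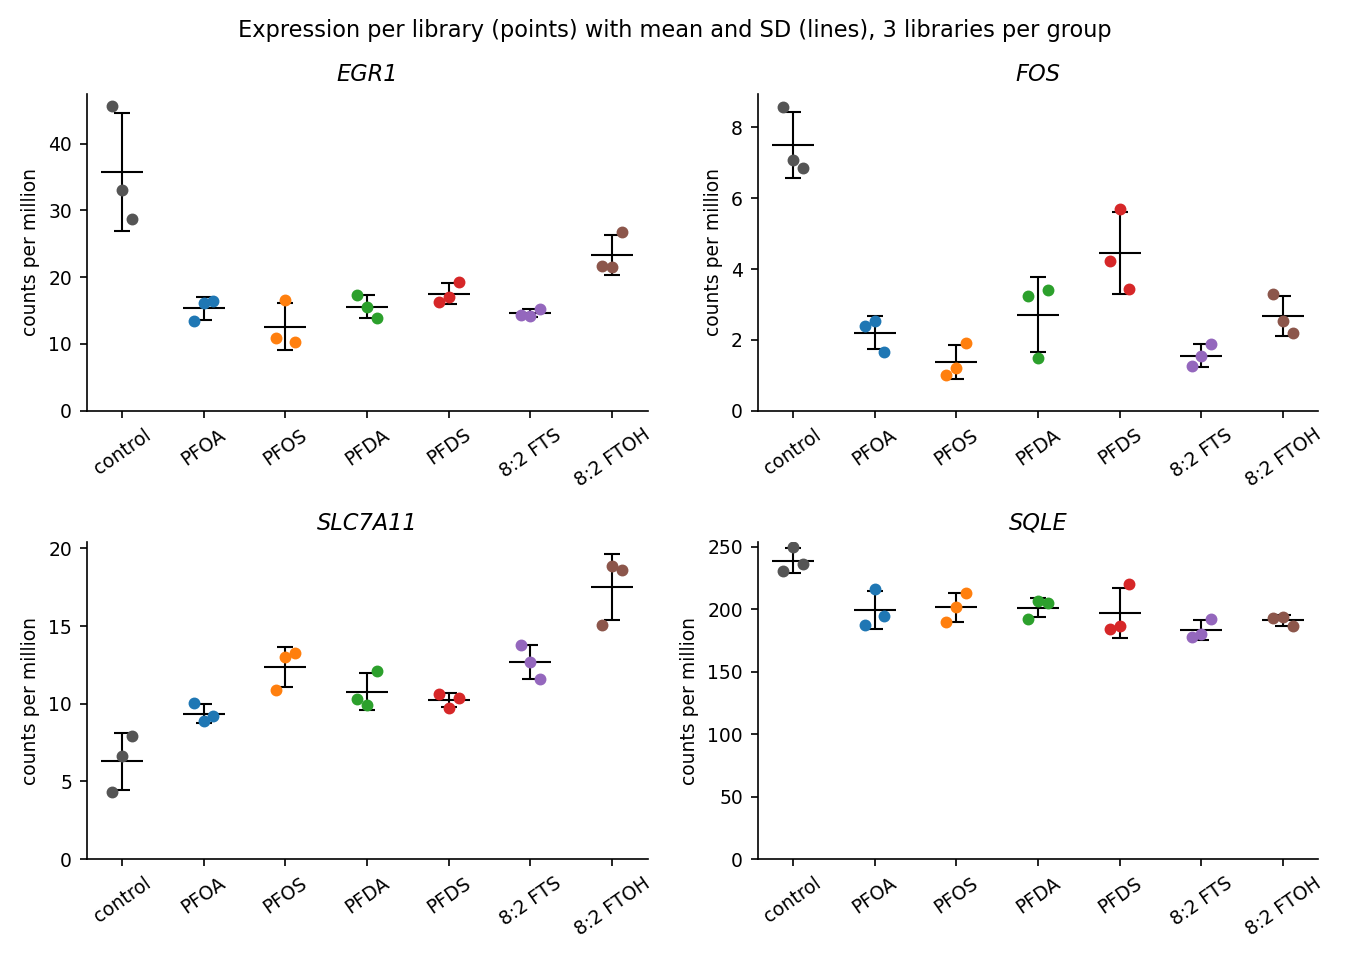
CPM of EGR1, FOS, SLC7A11 and SQLE in each of the 21 libraries (points), with the group mean (line) and SD (bar), n = 3 per group. EGR1 is at 35.8 ± 8.82 CPM in control and between 12.6 and 23.3 on average in the compound groups, and SLC7A11 is at 6.29 ± 1.82 in control and 17.5 ± 2.13 in 8:2 FTOH.

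Of 192 tests of gene lists against control (32 lists, 6 compounds), 88 passed with a preset correlation between genes of 0.01. With an estimated correlation, 0 of the 192 passed, the lowest adjusted p being 0.131, and with fry, which asks whether a list moves 1 way on balance, also 0, the lowest adjusted p being 0.0948. Each list result below is therefore a statement about these lists relative to other genes under the preset correlation only. The lists of PFOA were 16 lower and 0 higher, those of PFOS 9 lower and 3 higher, those of PFDA 14 and 1, those of PFDS 11 and 3, those of 8:2 FTS 14 and 2, and those of 8:2 FTOH 12 and 3. Median, mean and test direction differed in sign for 2 to 7 lists per compound, none of them among the 88.

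**Figure D3:**
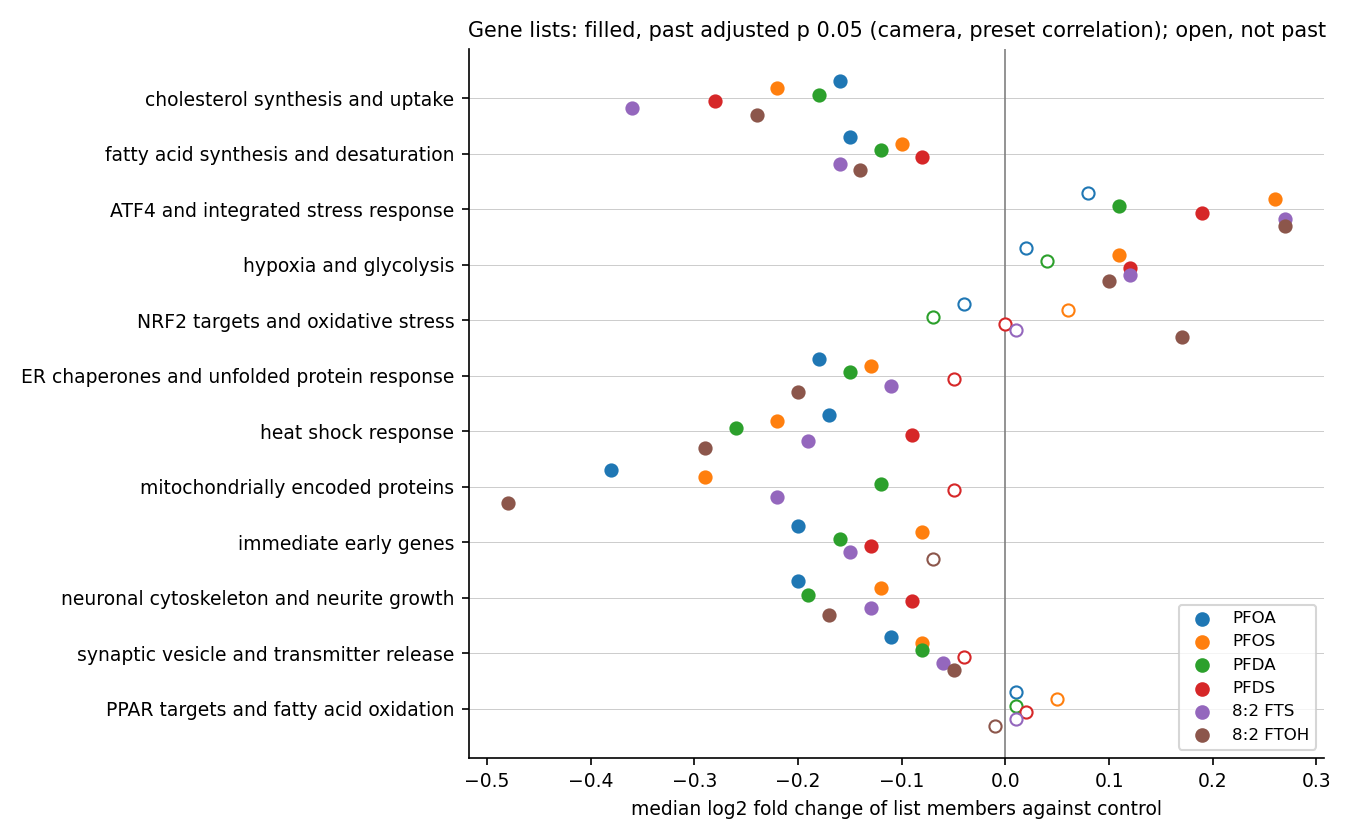
Median log2 fold change against control of 12 gene lists (horizontal axis) for the 6 compounds (colours), filled where the list test passed with the preset correlation. The cholesterol list lies between -0.36 and -0.16 for all 6 compounds, and the ATF4 list is highest for 8:2 FTS and 8:2 FTOH, at 0.27 each.

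EGR1 and FOS were lower with PFOA than in control. EGR1 (ENSG00000120738, chromosome 5, 138465479 to 138469303) fell from 35.8 CPM ± 8.82 to 15.4 ± 1.73, a log2 fold change of -1.21 (SE 0.15, adjusted p = 1.42e-05), and FOS (ENSG00000170345, chromosome 14, 75278826 to 75282230) fell from 7.5 CPM ± 0.934 to 2.2 ± 0.467 (log2 fold change -1.79, SE 0.28, adjusted p = 0.0011). The other calls were smaller and shared an adjusted p of 0.0324. Among them MAOB, which encodes the monoamine-degrading oxidase B, fell from 36.7 CPM ± 2.18 to 23.4 ± 3.38, and GPX4, which reduces lipid hydroperoxides, fell by 0.48 on the log2 scale. PRR36 fell by 0.44, and PTMS by 0.42, though PTMS overlaps MLF2 and counting ignored strand, so the gene is uncertain. The only rise was MIR137HG (log2 fold change 0.38), the host transcript of microRNA 137, which lies outside the naming rule, was named after its value was seen, and overlaps DPYD.

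Among the lists, neuronal cytoskeleton and neurite growth was lower for PFOA (adjusted p = 8.64e-14, and adjusted p = 0.267 with an estimated correlation). Of its 29 members, 26 had a negative fold change, 0 passed over all genes, and 14 fell when adjusted over the list alone. GAP43 was at 241 CPM ± 36.2 (log2 fold change -0.32), MAP1B at 4218 ± 563 (-0.36) and the collapsin response gene DPYSL3 at 639 ± 53.7 (-0.35), none past the threshold over all genes. Synaptic vesicle genes were also lower (adjusted p = 1.87e-06, and adjusted p = 0.223 with an estimated correlation; 6 of 27 lower when adjusted over the list alone), with SYP, the synaptophysin gene, at a log2 fold change of -0.28. The catecholamine and cholinergic list was lower (adjusted p = 7.66e-04, and adjusted p = 0.383 with an estimated correlation; 3 of 21 lower over the list alone, MAOB among them). Mitochondrially encoded proteins had a median log2 fold change of -0.38 (adjusted p = 4.11e-10, and adjusted p = 0.326 with an estimated correlation), and of -0.31 without the 2 libraries of highest mitochondrial share. MT-CYB, the cytochrome b gene, was at 2384 CPM ± 109 against 3192 ± 89.6. The small SD among the controls shows that the higher mitochondrial share of control replicate 3 did not lie in this gene. The ATF4 list did not pass for PFOA (adjusted p = 0.0843, median log2 fold change 0.08).

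The PFOA count was sensitive to single libraries: 2 genes passed without control replicate 1, without control replicate 2 or without PFOA replicate 1, 1 without PFOA replicate 3, 37 without PFOA replicate 2 and 139 without control replicate 3. DESeq2 called 128 genes, and scaling by library size alone gave 2 higher and 2 lower genes against 1 higher and 7 lower with TMM. FOS did not pass without PFOA replicate 3. MAOB, GPX4, PRR36, PTMS and MIR137HG did not pass without control replicate 1, control replicate 2, PFOA replicate 1 or PFOA replicate 3, nor, MIR137HG apart, under library size scaling. PTMS and MIR137HG were lost with a term for the replicate number as well.

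With PFOS, FOS and EGR1 were lower and SLC7A11 was higher than in control. FOS was at 1.38 CPM ± 0.486 (log2 fold change -2.49, SE 0.29, adjusted p = 9.09e-07) and EGR1 at 12.6 CPM ± 3.48 (-1.53, SE 0.15, adjusted p = 3.70e-08). SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349), the light chain of the cystine and glutamate exchanger, rose from 6.29 CPM ± 1.82 to 12.4 ± 1.3 (log2 fold change 0.97, SE 0.16, adjusted p = 0.00328); its antisense gene SLC7A11-AS1 overlaps it. The other 3 calls lie outside the naming rule and are named after their values were seen: RNVU1-25, a variant U1 small nuclear RNA gene of a multicopy family (log2 fold change -1.16), the unnamed gene ENSG00000287979 (-1.01), and DNM3OS, which overlaps DNM3 (0.55).

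The ATF4 and integrated stress response list was higher for PFOS (adjusted p = 2.89e-22, and adjusted p = 0.131 with an estimated correlation): 25 of 27 members had a positive fold change, 1 passed over all genes, and 17 rose when adjusted over the list alone. SLC7A5, the large neutral amino acid transporter, was at 121 CPM ± 9.75 against 92.3 ± 5.73 (log2 fold change 0.39) and STC2, a secreted stanniocalcin, at a log2 fold change of 0.60, neither past the threshold over all genes. Hypoxia and glycolysis genes were higher (adjusted p = 1.20e-07, and adjusted p = 0.326 with an estimated correlation; 2 of 24 over the list alone), with VEGFA at 0.38 and the glucose transporter gene SLC2A1 at 0.32. Without control replicate 1 they did not pass (adjusted p = 0.0517). Heat shock genes were lower (adjusted p = 4.83e-10, and adjusted p = 0.172 with an estimated correlation; 11 of 17 over the list alone), for instance the chaperone genes HSPA8 (log2 fold change -0.35) and DNAJA1 (-0.29). So were ER chaperones (adjusted p = 1.74e-06, and adjusted p = 0.355 with an estimated correlation; 4 of 23 over the list alone), where MANF was at -0.53 and PDIA3 at -0.34. Cholesterol genes were lower as well (adjusted p = 1.25e-12, and adjusted p = 0.267 with an estimated correlation; 8 of 23 over the list alone), with SQLE at -0.25 and ACAT2, which overlaps the more abundant TCP1 and SOD2 and is uncertain, at -0.34. The neuronal cytoskeleton list was lower at a median of -0.12 (adjusted p = 6.68e-08, and adjusted p = 0.336 with an estimated correlation; 2 of 29 over the list alone), and mitochondrially encoded genes by a median of -0.29 (adjusted p = 1.19e-08, and adjusted p = 0.326 with an estimated correlation), or -0.24 without the 2 libraries of highest mitochondrial share. Against control, the p53 target list passed for this compound only (adjusted p = 0.0361, and adjusted p = 0.326 with an estimated correlation) and not without control replicate 1 (0.212), PFOS replicate 1 (0.0558) or PFOS replicate 2 (0.198).

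Without control replicate 1 or without control replicate 2 the PFOS count was 3, without PFOS replicate 2 it was 2, and without control replicate 3 it was 24; without PFOS replicate 1 it was 4, and without PFOS replicate 3 it was 6. DESeq2 called 19 genes, and scaling by library size alone gave 5 higher and 4 lower genes against 2 higher and 4 lower with TMM. SLC7A11 did not pass without control replicate 1 or PFOS replicate 2, and EGR1 did not in a fit of only the groups compared. RNVU1-25 was lost without control replicate 2, PFOS replicate 1 or PFOS replicate 2, and ENSG00000287979 without control replicate 1, control replicate 2, PFOS replicate 2 or PFOS replicate 3. DNM3OS passed in 1 of the 6 fits that left out 1 library, that without control replicate 3, and not with a term for the replicate number.

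EGR1 and FOS were the 2 genes called for PFDA. EGR1 fell to 15.6 CPM ± 1.72 (log2 fold change -1.20, SE 0.15, adjusted p = 1.13e-05) and FOS to 2.71 CPM ± 1.05 (-1.42, SE 0.26, adjusted p = 0.0332). SLC7A11 was at 10.8 CPM ± 1.17 (log2 fold change 0.79) and did not pass (adjusted p = 0.0972). The lists with the lowest adjusted p were neuronal cytoskeleton and heat shock genes. Heat shock genes were lower (adjusted p = 1.07e-12, and adjusted p = 0.131 with an estimated correlation), with 16 of 17 members negative and 9 falling when adjusted over the list alone. HSPA8 was at 1004 CPM ± 39.4 against 1330 ± 149, HSP90AA1 at a log2 fold change of -0.31 and the co-chaperone gene STIP1 at -0.27. ER chaperones were lower too (adjusted p = 8.88e-08, and adjusted p = 0.326 with an estimated correlation; 2 of 23 over the list alone), with PDIA3 at -0.35. The neuronal cytoskeleton list had 27 of 29 negative members (adjusted p = 7.73e-14, and adjusted p = 0.267 with an estimated correlation), 9 of them falling over the list alone, with GAP43 at -0.35 and DPYSL3 at -0.31. Cytosolic ribosomal proteins, 40 of 44 negative, were lower at a median of -0.11 (adjusted p = 2.43e-07, and adjusted p = 0.572 with an estimated correlation), which became -0.06 without control replicate 3 and -0.05 under library size scaling. Mitochondrially encoded genes were lower at a median of -0.12 (adjusted p = 6.35e-05, and adjusted p = 0.470 with an estimated correlation), but not without PFDA replicate 3 (adjusted p = 0.811). That median was -0.07 without control replicate 3, -0.06 without the 2 libraries of highest mitochondrial share and -0.05 under library size scaling. The ATF4 list was higher by a median of 0.11 (adjusted p = 2.40e-04, and adjusted p = 0.437 with an estimated correlation; 2 of 27 over the list alone). That call was lost without control replicate 1 (adjusted p = 0.648) or PFDA replicate 3 (0.125), and the median was 0.18 without control replicate 3 and 0.17 under library size scaling.

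For PFDA, 1 gene passed without control replicate 1, without control replicate 2 or without any 1 of the 3 PFDA libraries, and 21 without control replicate 3. DESeq2 called 23 genes, and scaling by library size alone gave 2 higher and 1 lower against 0 higher and 2 lower with TMM. EGR1 passed in each of these fits for which it had a value. FOS did not pass without control replicate 1, control replicate 2 or any 1 of the 3 PFDA libraries, nor under library size scaling or with a term for the replicate number.

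PFDS differed from control at 6 genes, EGR1 among them. EGR1 fell to 17.5 CPM ± 1.53 (log2 fold change -1.02, SE 0.15, adjusted p = 6.13e-04). ARSJ, an arylsulfatase gene, fell by 0.86 on the log2 scale (adjusted p = 0.013), INHBA, which encodes the activin A subunit, by 0.67 and the growth factor gene FGF1 by 0.49 (both adjusted p = 0.0147), and the cadherin gene CDH20 by 0.96 (adjusted p = 0.0383). NTNG2, a netrin-G gene of axon guidance, rose by 0.53 (adjusted p = 0.03). FGF1 is uncertain because SPRY4-AS1 overlaps it. FOS, at 4.45 CPM ± 1.15, did not pass for PFDS (log2 fold change -0.77, adjusted p = 0.579).

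Genes of cholesterol synthesis and uptake were lower for PFDS (adjusted p = 4.73e-25, and adjusted p = 0.131 with an estimated correlation): 22 of 23 members were negative, 0 passed over all genes, and 14 fell when adjusted over the list alone. ACAT2, uncertain for its overlaps, was at 74.6 CPM ± 17.7 against 103 ± 11.3, and IDI1 at a log2 fold change of -0.33. Hypoxia and glycolysis genes were higher (adjusted p = 6.61e-09, and adjusted p = 0.326 with an estimated correlation), with 24 of 24 members positive and 2 rising over the list alone, SLC2A1 at 0.36 among the largest. The ATF4 list was higher by a median of 0.19 (adjusted p = 4.92e-12, and adjusted p = 0.253 with an estimated correlation; 7 of 27 over the list alone), or 0.29 without control replicate 3, with SLC7A11 at 0.71 and SLC7A5 at 0.38. The neuronal cytoskeleton list was lower (adjusted p = 2.01e-08, and adjusted p = 0.326 with an estimated correlation; 7 of 29 over the list alone), with NEFM, which overlaps ENSG00000272163, at 125 CPM ± 14.2 (log2 fold change -0.56) and GAP43 at -0.38. Heat shock genes were lower at a median of -0.09 (adjusted p = 0.0025, and adjusted p = 0.419 with an estimated correlation; 0 of 17 over the list alone). The call was lost without control replicate 2 (0.154) or PFDS replicate 2 (0.284). ER chaperones (adjusted p = 0.195) and mitochondrially encoded genes (adjusted p = 0.435, median -0.05) did not pass. Axon guidance genes were higher by 0.08 (adjusted p = 0.00243, and adjusted p = 0.336 with an estimated correlation), though not without PFDS replicate 3 (0.315).

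The PFDS count was 3 without control replicate 1, 1 without control replicate 2, 23 without control replicate 3, 4 without PFDS replicate 1 or PFDS replicate 2, and 101 without PFDS replicate 3. DESeq2 called 34 genes, and scaling by library size alone gave 5 higher and 8 lower against 1 higher and 5 lower with TMM. ARSJ, INHBA, FGF1, CDH20 and NTNG2 did not pass without control replicate 2 or in a fit of only the groups compared. All but NTNG2 were lost without control replicate 1 or PFDS replicate 1, all but ARSJ without PFDS replicate 2, and NTNG2 without control replicate 3.

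For 8:2 FTS 21 genes were called, 4 of the cholesterol list among them. SQLE (ENSG00000104549, chromosome 8, 124998497 to 125022283), which encodes squalene epoxidase, fell from 239 CPM ± 9.98 to 183 ± 7.93 (log2 fold change -0.38, SE 0.07, adjusted p = 0.016). The sterol desaturase gene SC5D fell by 0.39 (adjusted p = 0.0169), the methylsterol oxidase gene MSMO1 by 0.50 (adjusted p = 0.0251) and INSIG1, which retains the sterol-sensing complex in the endoplasmic reticulum, by 0.43 (adjusted p = 0.0343). ERG28, a sterol synthesis scaffold that overlaps TTLL5, fell by 0.53 (adjusted p = 0.0192). These calls depended on single libraries. MSMO1 and INSIG1 did not pass in any of the 6 fits that left out 1 library, nor without the 2 libraries absent from the authors' table, and SC5D passed in 1 of the 6, the fit without control replicate 3. SQLE did not pass without control replicate 2, 8:2 FTS replicate 1 or 8:2 FTS replicate 2, nor did ERG28, which was also lost without control replicate 1. In the list of 23 cholesterol genes all were negative, 4 passed over all genes and 17 fell when adjusted over the list alone (adjusted p = 2.85e-26, and adjusted p = 0.131 with an estimated correlation). Genes of fatty acid synthesis and desaturation were lower as well (adjusted p = 1.53e-05, and adjusted p = 0.326 with an estimated correlation; 5 of 16 over the list alone).

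Of the amino acid transporters, SLC7A11 rose to 12.7 CPM ± 1.09 for 8:2 FTS (log2 fold change 1.02, SE 0.16, adjusted p = 0.00143) and SLC7A5 to 128 ± 19.5 (0.48, SE 0.09, adjusted p = 0.016). They are the 2 members of the ATF4 list past the threshold over all genes. Of its 27 members 15 rose when adjusted over the list alone (adjusted p = 3.44e-17, and adjusted p = 0.172 with an estimated correlation), and PHGDH, the entry enzyme of serine synthesis, was at 0.35. EGR1 fell to 14.6 CPM ± 0.59 (log2 fold change -1.30, adjusted p = 3.29e-06), FOS to 1.56 ± 0.315 (-2.29, adjusted p = 9.53e-06) and the kinase gene PLK2 by 0.62 (adjusted p = 0.00832). PFDN4, a prefoldin subunit gene, fell by 0.61 (adjusted p = 0.0446) and NIM1K from 2.21 CPM ± 0.0675 to 0.482 ± 0.161 (adjusted p = 0.0227). GALR2, a galanin receptor gene that overlaps ZACN, passed at 0.0673 CPM against 1.09, too few reads for a fold change. The 8 other calls lie outside the naming rule: TMEM97 (-0.46, overlapping IFT20), TBX3 (-0.40), DKK2 (-0.45, overlapping an unnamed gene), the small RNA genes U3 (-0.81) and RNVU1-25 (-0.96), and ENSG00000290960 (1.83), ENSG00000260368 (-1.45) and ENSG00000279602 (-0.52), all named after their values were seen. Heat shock genes were lower (adjusted p = 1.02e-08, and adjusted p = 0.219 with an estimated correlation; 7 of 17 over the list alone; HSP90AA1 -0.36), as was the neuronal cytoskeleton list (adjusted p = 8.16e-10, and adjusted p = 0.326 with an estimated correlation; 8 of 29 over the list alone; GAP43 -0.38). Hypoxia and glycolysis genes were higher (adjusted p = 1.04e-07, and adjusted p = 0.326 with an estimated correlation; 4 of 24 over the list alone; VEGFA 0.36). Replication-dependent histone genes, 16 of 16 negative, were lower at a median of -0.27 (adjusted p = 3.00e-08, and adjusted p = 0.364 with an estimated correlation). Mitochondrially encoded genes were lower at a median of -0.22 (adjusted p = 4.20e-05, and adjusted p = 0.455 with an estimated correlation), and -0.16 without the 2 libraries of highest mitochondrial share. ER chaperones passed (adjusted p = 0.00129, and adjusted p = 0.539 with an estimated correlation) but not without control replicate 2 (0.0691) or 8:2 FTS replicate 2 (0.732).

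The 8:2 FTS count was 9 without control replicate 1, 4 without control replicate 2 and 44 without control replicate 3, and 3, 6 and 13 without 8:2 FTS replicates 1, 2 and 3. DESeq2 called 49 genes, and scaling by library size alone gave 13 higher and 15 lower against 3 higher and 18 lower with TMM. SLC7A11 did not pass without 8:2 FTS replicate 1, SLC7A5 without control replicate 1, control replicate 2, 8:2 FTS replicate 1 or 8:2 FTS replicate 3, and PLK2 without control replicate 2, 8:2 FTS replicate 1 or 8:2 FTS replicate 3. U3 was lost without control replicate 2 or 8:2 FTS replicate 2. The next genes were all lost without 8:2 FTS replicate 1 or 8:2 FTS replicate 2: DKK2, TMEM97 and ENSG00000290960 also without control replicate 1 or 2, NIM1K, RNVU1-25 and TBX3 also without control replicate 1, control replicate 2 or 8:2 FTS replicate 3, PFDN4 and ENSG00000279602 also without control replicate 2, control replicate 3 or 8:2 FTS replicate 3, ENSG00000260368 also without control replicate 1, control replicate 3 or 8:2 FTS replicate 3, and GALR2 without any 1 of the 6 libraries. PFDN4, GALR2, TBX3 and ENSG00000279602 did not pass under library size scaling. Of the 21 calls, 20 were kept with DESeq2 size factors or in a fit of only the groups compared. With the stricter filter or with a term for the replicate number 19 were kept, and 16 without the 2 libraries absent from the authors' table.

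SLC7A11 was higher with 8:2 FTOH than in control, at 17.5 CPM ± 2.13 against 6.29 ± 1.82 (log2 fold change 1.48, SE 0.16, adjusted p = 3.21e-07). FOS fell to 2.67 CPM ± 0.562 (-1.48, SE 0.28), PLK2 by 0.62 and the cadherin gene CDH11 by 0.45, all at an adjusted p of 0.02. TCEAL5 fell by 0.81 (adjusted p = 0.0258), the HSP90 co-chaperone gene CHORDC1 by 0.41 (adjusted p = 0.0373), and ATP5PF, an ATP synthase subunit gene that overlaps GABPA, by 0.54 (adjusted p = 0.0471). RNVU1-25, outside the naming rule and named after its value was seen, fell by 0.98 (adjusted p = 0.0471). EGR1 was at 23.3 CPM ± 2.97 (log2 fold change -0.63) and did not pass (adjusted p = 0.092).

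The ATF4 list was higher for 8:2 FTOH (adjusted p = 5.21e-16, and adjusted p = 0.172 with an estimated correlation), with 25 of 27 members positive, 1 past over all genes and 14 rising when adjusted over the list alone; SLC7A5 was at 124 CPM ± 8.49 (0.43). NRF2 targets, genes of the antioxidant response, passed against control for this compound only (adjusted p = 2.16e-04, and adjusted p = 0.326 with an estimated correlation): 16 of 22 were positive, and over the list alone 5 rose and 2 fell. TXNRD1, the thioredoxin reductase gene, was at a log2 fold change of 0.30 and the malic enzyme gene ME1 at 0.39. Heat shock genes were lower at a median of -0.29 (adjusted p = 2.16e-13, and adjusted p = 0.131 with an estimated correlation), 16 of 17 being negative, 1 past over all genes (CHORDC1) and 11 over the list alone. All 23 cholesterol genes were negative (adjusted p = 4.95e-15, and adjusted p = 0.225 with an estimated correlation; 11 falling over the list alone), with NSDHL at -0.49 and SQLE at -0.32. Mitochondrially encoded genes were lower at a median of -0.48 (adjusted p = 2.42e-18, and adjusted p = 0.219 with an estimated correlation), 9 of 13 over the list alone, with MT-CYB at 2293 CPM ± 151. The median was -0.40 without the 2 libraries of highest mitochondrial share. The neuronal cytoskeleton list was lower (adjusted p = 1.57e-09, and adjusted p = 0.326 with an estimated correlation), 6 of 29 falling and 1 rising over the list alone. NEFM, which overlaps an unnamed gene, was at -0.59, and UCHL1, the neuronal ubiquitin hydrolase gene, at 0.34. ER chaperones were lower (adjusted p = 5.85e-05, and adjusted p = 0.425 with an estimated correlation; 4 of 23 over the list alone; MANF -0.59). Hypoxia and glycolysis genes were higher (adjusted p = 1.64e-04, and adjusted p = 0.467 with an estimated correlation; 1 of 24 over the list alone). That was not so without control replicate 1 (0.588) or 8:2 FTOH replicate 2 (0.0668).

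The 8:2 FTOH count was 2 without control replicate 1, 1 without control replicate 2, 32 without control replicate 3, 15 without 8:2 FTOH replicate 1, and 1 without 8:2 FTOH replicate 2 or 8:2 FTOH replicate 3. DESeq2 called 59 genes, and scaling by library size alone gave 4 higher and 4 lower against 1 higher and 7 lower with TMM. SLC7A11 passed in 14 of 14 alternatives for this compound. The other 7 calls did not pass without control replicate 2, 8:2 FTOH replicate 2 or 8:2 FTOH replicate 3. All of them but CHORDC1 were lost without control replicate 1, CHORDC1 without control replicate 3, and CHORDC1 and RNVU1-25 without 8:2 FTOH replicate 1. CHORDC1, ATP5PF and RNVU1-25 did not pass under library size scaling, nor did these 3, FOS and TCEAL5 without the 2 libraries absent from the authors' table. Of the 8 calls, 6 were kept with DESeq2 size factors, and also 6 with the stricter filter and 6 with a term for the replicate number.

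**Figure D4:**
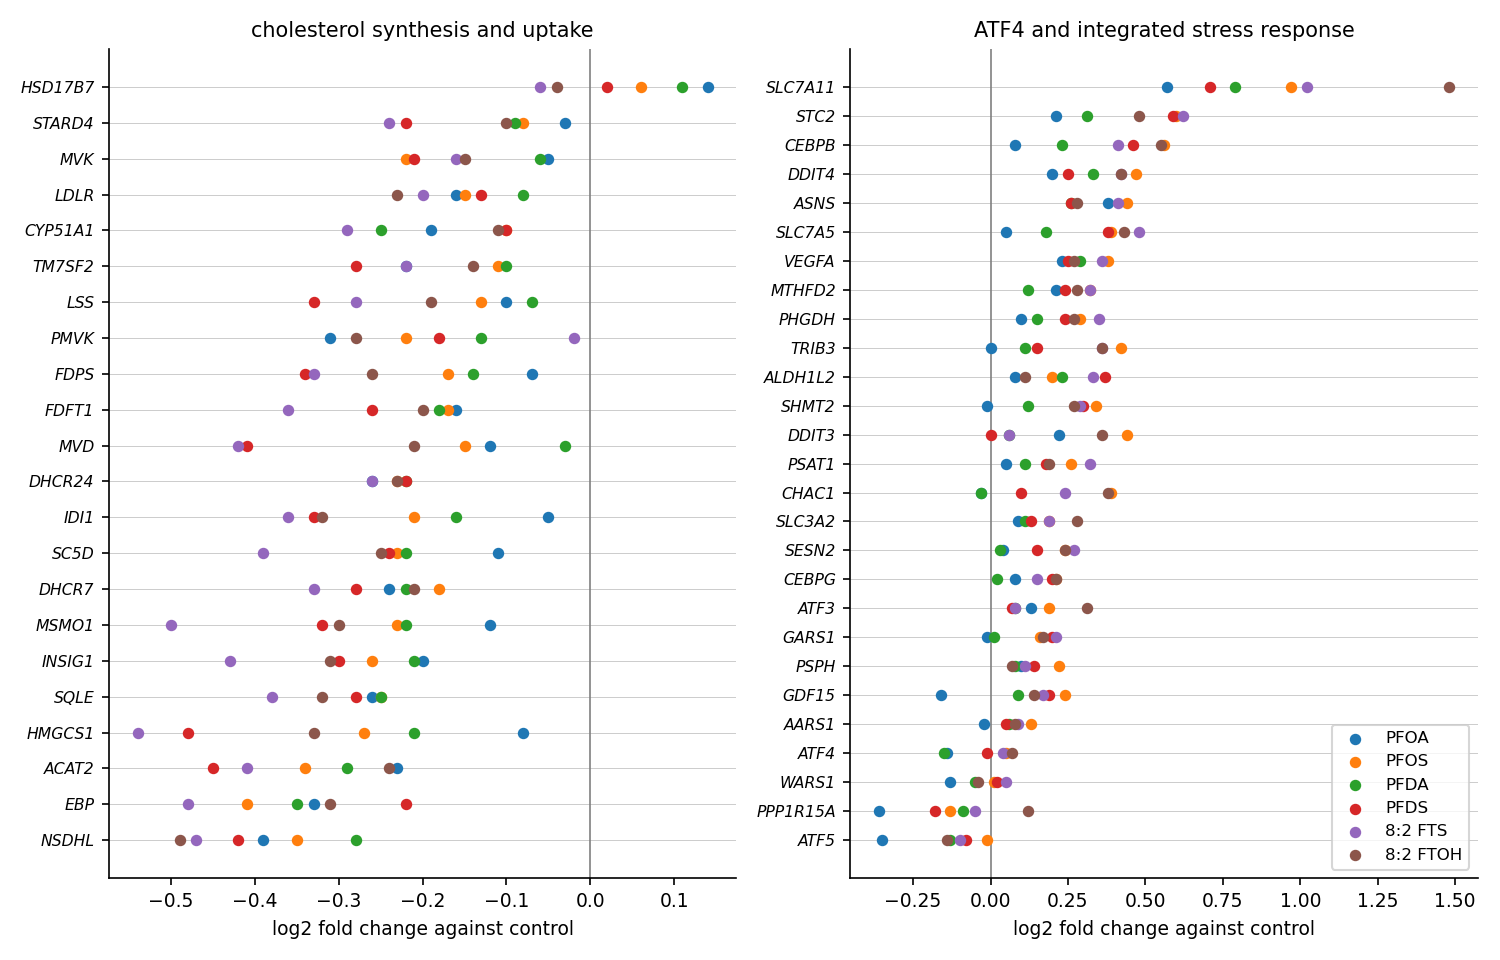
Log2 fold change against control (horizontal axis) of members of the cholesterol list and of the 27 genes of the ATF4 list, with 1 line per gene and 1 point per compound. Every cholesterol gene drawn lies below 0 for 8:2 FTS and 8:2 FTOH, all but 1 do for the other compounds, and 25 of 27 ATF4 genes lie above 0 for PFOS, 8:2 FTS and 8:2 FTOH.

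Across compounds, the cholesterol list was also lower for PFOA (adjusted p = 1.74e-06, and adjusted p = 0.370 with an estimated correlation; 3 of 23 over the list alone) and PFDA (adjusted p = 2.34e-08, and adjusted p = 0.326 with an estimated correlation; 1 of 23 over the list alone). It thus passed for all 6 compounds, and did so with any 1 library left out. Fatty acid synthesis genes were lower for PFOA (adjusted p = 4.80e-05), PFOS (0.00106, but 0.0838 without PFOS replicate 1), PFDA (4.98e-04), PFDS (7.70e-04, but 0.4 without PFDS replicate 1) and 8:2 FTOH (0.00173); with an estimated correlation the adjusted p was 0.326, 0.419, 0.386, 0.408 and 0.425. Heat shock genes and ER chaperones were lower for PFOA as well, each at an adjusted p of 4.33e-06 (adjusted p = 0.326 and 0.371 with an estimated correlation), 5 of 17 and 1 of 23 over the list alone. The immediate early list, 16 genes, was lower for PFOA (adjusted p = 2.33e-04), PFOS (0.00525), PFDA (0.00341), PFDS (0.00761, but 0.454 without PFDS replicate 1) and 8:2 FTS (0.00255), and not for 8:2 FTOH (0.312); with an estimated correlation the adjusted p was 0.267 for PFOA and 0.326 for the other 4. Cell cycle genes, which mark proliferating cells, were lower for all 6 compounds, with adjusted p between 1.03e-08 (PFOS) and 0.0206 (PFDS) and between 0.326 and 0.751 with an estimated correlation. MKI67 was at 686 CPM ± 65.2 for PFOA and 704 ± 36.6 for PFOS. The PFDS cell cycle call was lost without control replicate 2 (0.532), PFDS replicate 1 (0.295) or PFDS replicate 2 (0.564), and under library size scaling (0.071), where the median of -0.06 became -0.03.

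Other neuronal lists passed for fewer than the 6 compounds. Synaptic vesicle genes were lower for PFOS (adjusted p = 0.00326, and adjusted p = 0.353 with an estimated correlation), PFDA (1.64e-04; 0.326) and 8:2 FTOH (0.00327; 0.353), the last not without 8:2 FTOH replicate 1 (0.0724). For 8:2 FTS the same list passed at 0.0361 (adjusted p = 0.496 with an estimated correlation) but not without control replicate 1 (0.135), control replicate 2 (0.0523), 8:2 FTS replicate 2 (0.126) or 8:2 FTS replicate 3 (0.0568), nor under library size scaling (0.309), where the median of -0.06 became -0.01. Axon guidance genes were lower for PFOA (adjusted p = 0.00177, and adjusted p = 0.326 with an estimated correlation), where the median of -0.05 became 0.02 when scaled by library size. Voltage-gated channel and calcium genes passed for 8:2 FTOH only (adjusted p = 0.0418, and adjusted p = 0.326 with an estimated correlation), with a median of -0.04 that became -0.08 without control replicate 3. The call was lost under library size scaling (0.218, median 0.00), in a fit of only the groups compared (0.0522), and without control replicate 1 (0.26), control replicate 2 (0.0571) or 8:2 FTOH replicate 1 (0.335). Genes linked to neurodegeneration were lower for PFOA (adjusted p = 0.00647, and adjusted p = 0.425 with an estimated correlation; 0.0607 without PFOA replicate 3) and PFDA (0.0159; 0.480; 0.0731 without control replicate 3 and 0.0716 without PFDA replicate 2), where the medians of -0.09 and -0.07 became -0.02 and -0.00 under library size scaling. Neither call held under that scaling (adjusted p = 0.11 and 0.206) or without the 2 libraries absent from the authors' table (0.0613 and 0.0903). Retinoic acid response genes were lower for 8:2 FTS (adjusted p = 0.00111, and adjusted p = 0.381 with an estimated correlation; 2 of 12 over the list alone) and PFDS (0.00341; 0.425), the latter with its sign turned without PFDS replicate 1 (0.759). Glial and Schwann markers, a list for another cell type, did not pass for any compound (lowest adjusted p = 0.381, PFOA).

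Several lists passed only while particular libraries were included. Ribosomal protein genes were lower for PFOA (adjusted p = 0.00451, median -0.06 and 0.01 under library size scaling), PFDS (9.71e-04), 8:2 FTS (2.33e-04) and 8:2 FTOH (0.00173), with adjusted p of 0.804, 0.770, 0.751 and 0.782 with an estimated correlation. Without control replicate 3 the adjusted p was 0.291, 0.189, 0.0693 and 0.18, and without control replicate 2 it was 0.687, 0.679, 0.413 and 0.637; PFOA also lost the call without PFOA replicate 3 (0.0778). Without 8:2 FTOH replicate 3 the 8:2 FTOH list turned higher (0.284), and so did the PFDS list without PFDS replicate 1 (0.191). Nuclear-encoded oxidative phosphorylation genes were lower for PFDA (adjusted p = 0.0106, and adjusted p = 0.751 with an estimated correlation; median -0.06 and 0.01 under library size scaling), 8:2 FTS (0.0136; 0.751) and PFDS (1.60e-05; 0.447). Without control replicate 3 the PFDA and 8:2 FTS values were 0.133 and 0.145, without control replicate 2 they were 0.38 and 0.391, without PFDA replicate 1 0.291, without 8:2 FTS replicate 2 0.124, and the PFDS value was 0.664 without PFDS replicate 1. Autophagy genes passed for PFOA (adjusted p = 0.0322, and adjusted p = 0.537 with an estimated correlation; median -0.07 and -0.00 under library size scaling), though not without control replicate 3 (0.0913), PFOA replicate 1 (0.19) or PFOA replicate 3 (0.0586). Mesenchymal-like markers, for another state of neuroblastoma cells, were lower for PFOA (adjusted p = 1.43e-04, and adjusted p = 0.172 with an estimated correlation), with any 1 library left out too, and for 8:2 FTS (0.0429; 0.364). The 8:2 FTS call was kept in 0 of the 6 fits that left out 1 library, whose adjusted p ran from 0.0508 to 0.0999. They also passed for PFDA (0.024; adjusted p = 0.326 with an estimated correlation; 0.0612 without control replicate 3), PFDS (0.0316; 0.336; 0.0692, 0.0851, 0.802 and 0.0735 without control replicate 2, control replicate 3, PFDS replicate 1 and PFDS replicate 2) and 8:2 FTOH (0.0202, 0.326, 0.0572 without control replicate 3 and 0.103 without 8:2 FTOH replicate 3), where the median became 0.00 when scaled by library size. Histone genes were lower for PFOA (adjusted p = 0.0194, and adjusted p = 0.770 with an estimated correlation; 0.681 without control replicate 2 and 0.133 without PFOA replicate 3), PFDA (0.00109; 0.629; 0.273 without control replicate 2 and 0.132 without PFDA replicate 1), PFDS (1.55e-06; 0.425; 0.88 without PFDS replicate 1, with the sign turned) and 8:2 FTOH (2.05e-04; 0.551; 0.112 without control replicate 2 and 0.652 without 8:2 FTOH replicate 3). Some of these calls were also lost under library size scaling: ribosomal proteins for PFOA (adjusted p = 0.155), oxidative phosphorylation for PFDA (0.105) and 8:2 FTS (0.106), and autophagy for PFOA (0.16). Without the 2 libraries absent from the authors' table, the adjusted p was 0.3 for ribosomal proteins of PFOA, 0.231 for those of PFDS and 0.0613 for those of 8:2 FTS. In the same fit it was 0.128 and 0.133 for oxidative phosphorylation of PFDA and 8:2 FTS, 0.108 for autophagy of PFOA and 0.262 for histones of 8:2 FTOH. Mesenchymal-like markers were then at 0.0571 for PFDA, 0.0841 for PFDS and 8:2 FTS and 0.164 for 8:2 FTOH. Lists that passed against control for no compound were PPAR targets (lowest adjusted p = 0.212), LXR targets (0.325), glycerophospholipid synthesis (0.153), sphingolipid metabolism (0.38), metallothioneins (0.0974), xenobiotic metabolism (0.359), inflammation (0.557) and apoptosis regulators (0.339).

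**Figure D5:**
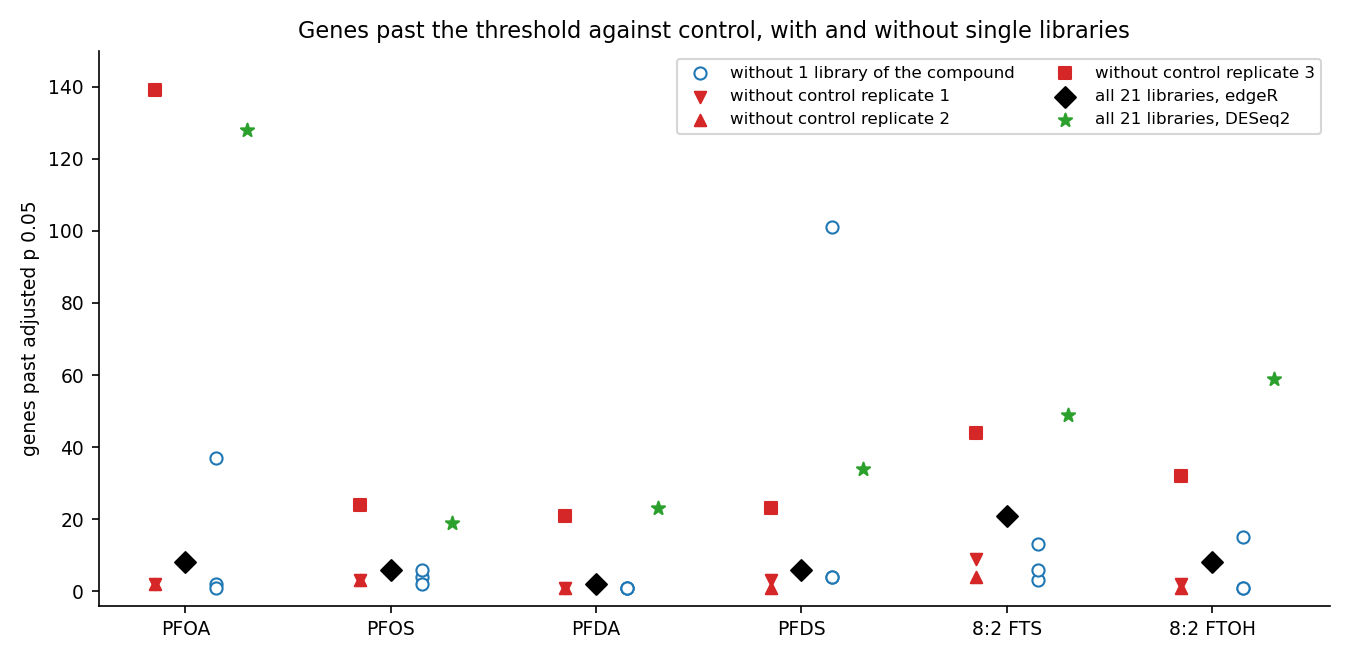
Number of genes past an adjusted p of 0.05 for each compound against control: all libraries with edgeR and with DESeq2, and edgeR without each control library and without each library of the compound. Leaving out control replicate 3 raises the count for all 6 compounds (to 139 for PFOA, 24 for PFOS, 21 for PFDA, 23 for PFDS, 44 for 8:2 FTS and 32 for 8:2 FTOH), while control replicates 1 and 2 lower it.

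How far the compounds moved genes alike was measured over all 24879 genes. The 15 pairs of comparisons had Pearson correlations of log2 fold changes from 0.44 to 0.62 (median 0.52), across genes, which are not independent replicates. Unchanged groups simulated against 3 shared simulated controls gave means over 20 simulations of 0.45 to 0.49 per pair, because comparisons with shared controls correlate. The highest single simulated value was 0.50. All 21 libraries were drawn with 1 mean and 1 spread per gene, so the real controls did not enter. The covariance was 0.0573 to 0.08, against simulated means of 0.0497 to 0.0507 and a highest single simulated value of 0.0543. In all 15 pairs the observed value exceeded the highest of the 20 simulated ones, and it lay 0.0071 to 0.0299 over the simulated mean. With the stricter filter (19790 genes) it was 0.0289 to 0.048 (median 0.0365, where it had been 0.0668), against 0.0246 to 0.0253 simulated, again above the highest simulated value in 15 of 15 pairs, by 0.0039 to 0.023 over the simulated mean. By Pearson correlation this did not hold for every pair: PFDS with 8:2 FTOH was at 0.44 (highest simulated 0.47), PFOA with 8:2 FTOH at 0.47 (0.48) and PFOA with PFDS at 0.48 (0.48). The share of genes with the same sign was 64.4% to 73.6%, against simulated means of 65.4% to 66.2%, and for PFOA with PFDS it was below the simulated mean. Of called genes, pairs shared 0 to 3 lower and 0 to 1 higher, where the simulated groups shared 0.05 or fewer on average. The simulated groups had no differences and so few calls to share, which means that this contrast does not measure sharing between compounds. The simulation does not carry traits of the 3 real controls, which cannot be split into groups of 2 or more. Part or all of the excess may therefore come from the shared controls.

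Chain length was compared within each head group at matched dose and time. Between the carboxylates, PFDA and PFOA, edgeR called 0 genes (729 at an unadjusted p under 0.05), DESeq2 also 0, and the smallest adjusted p was 1. EGR1 differed by 0.01 (95% interval -0.30 to 0.33), FOS by 0.38 (-0.22 to 0.97), SLC7A11 by 0.21 (-0.11 to 0.54) and SQLE by 0.01 on the log2 scale. Of the 32 lists 6 passed, with an adjusted p of 0.989 for each with an estimated correlation. Mitochondrially encoded genes were higher in PFDA by a median of 0.23 (adjusted p = 0.00336). They did not pass without PFOA replicate 1 (0.0718), and without PFDA replicate 2, a library of high mitochondrial share, they were lower (0.00166). In PFDA, heat shock genes were lower at a median of -0.07 (0.0184), not so without PFDA replicate 1 (0.133) or PFOA replicate 2 (0.282), and apoptosis regulators by -0.08 (0.0295), lost without PFDA replicate 1 (0.0852), PFDA replicate 2 (0.0662), PFOA replicate 1 (0.087) or PFOA replicate 2 (0.11).

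Between the sulfonates, FOS was the only gene that passed: it was at 4.45 CPM ± 1.15 for PFDS and 1.38 ± 0.486 for PFOS, a difference of 1.72 on the log2 scale (SE 0.30, 95% interval 1.11 to 2.33, adjusted p = 0.0253). DESeq2 called 2 genes. The FOS call held without PFDS replicate 3 (3 genes) or PFOS replicate 3 (1 gene) but 0 genes passed without PFDS replicate 1, PFOS replicate 1 or PFOS replicate 2, and without PFDS replicate 2 the 1 call was another gene. Nor did FOS pass under library size scaling (0 genes) or in a fit of only the groups compared (6 other genes). EGR1 was higher in PFDS by 0.50 (0.19 to 0.82) without passing. Of the lists 10 passed, each at an adjusted p of 0.989 with an estimated correlation. In PFDS, mitochondrially encoded genes were higher by a median of 0.26 (adjusted p = 4.01e-06; 0.162 without PFDS replicate 1), ATF4 genes lower at a median of -0.08 (0.00337; 0.081 without PFDS replicate 2) and cholesterol genes lower at a median of -0.09 (0.00287), the last with the sign turned without PFDS replicate 1 (0.237) and no call without PFOS replicate 2 (0.107).

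Whether the chain length effect differed between sulfonates and carboxylates was tested as an interaction over the 4 groups. edgeR called 0 genes (869 at an unadjusted p under 0.05) and DESeq2 0, and the intervals were wider here, with a median distance of 0.42 from estimate to bound. FOS had the interaction 1.34 (0.49 to 2.20) and SLC7A11 -0.47 (-0.94 to -0.01), neither past the threshold. Of 32 lists, 5 passed, and their values are given in the closing section.

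Head group was compared within the shorter and within the longer pair, which are matched by total number of carbons. Other differences within a pair, such as the length of the perfluorinated tail, were not separated from the head group. Between PFOS and PFOA, edgeR and DESeq2 both called 0 genes (1220 at an unadjusted p under 0.05 with edgeR; smallest adjusted p = 0.958). SLC7A11 differed by 0.39 (95% interval 0.06 to 0.72), FOS by -0.70 (-1.35 to -0.05) and EGR1 by -0.31 (-0.63 to 0.01) on the log2 scale, none past the threshold. The ATF4 list was higher in PFOS (adjusted p = 8.76e-15, and adjusted p = 0.989 with an estimated correlation), with 27 of 27 members positive, 3 rising over the list alone and the call kept with any 1 library left out. SLC7A5 differed by 0.34 (0.15 to 0.52) and SHMT2, the mitochondrial serine hydroxymethyltransferase gene, by 0.35 (0.15 to 0.55). Hypoxia and glycolysis genes were higher in PFOS by a median of 0.12 (adjusted p = 1.42e-05) and axon guidance genes by 0.09 (1.51e-05), both also kept with any 1 library left out and both at an adjusted p of 0.989 with an estimated correlation; ALDOA, the aldolase gene, differed by 0.52 (0.25 to 0.79). The neuronal cytoskeleton list was higher in PFOS by 0.08, or 0.05 under library size scaling (0.00469; adjusted p = 0.989 with an estimated correlation), but not without PFOA replicate 1 (0.379), PFOA replicate 3 (0.0991) or PFOS replicate 2 (0.0964). Mesenchymal-like markers, for another cell state, were higher in PFOS too, by 0.16 (adjusted p = 0.00822, and adjusted p = 0.989 with an estimated correlation), with any 1 library left out as well (0.00833 to 0.0417).

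Between PFDS and PFDA, edgeR and DESeq2 called 0 genes (1390 at an unadjusted p under 0.05 with edgeR; smallest adjusted p = 0.402), and 1 passed without PFDS replicate 2. FOS differed by 0.65 (95% interval 0.09 to 1.20), EGR1 by 0.18 and SLC7A11 by -0.08 on the log2 scale, none past the threshold. Compared with PFDA, in PFDS heat shock genes were higher by a median of 0.14 (adjusted p = 1.63e-05) and ER chaperones by 0.11 (7.74e-05), or 0.07 under library size scaling, each kept with any 1 library left out and each at an adjusted p of 0.989 with an estimated correlation. HSPA8 differed by 0.27 (0.06 to 0.47). Cholesterol genes were lower in PFDS at a median of -0.11 (adjusted p = 4.02e-05, and adjusted p = 0.989 with an estimated correlation), but not without PFDS replicate 1 (0.986).

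The fluorotelomers 8:2 FTS and 8:2 FTOH differ in head group. edgeR called 0 genes between them (811 at an unadjusted p under 0.05; smallest adjusted p = 0.203), and DESeq2 3. Between 8:2 FTS and 8:2 FTOH, EGR1 differed by -0.66 (95% interval -0.98 to -0.34), FOS by -0.82 (-1.47 to -0.17) and SLC7A11 by -0.46 (-0.78 to -0.14), without passing. NRF2 targets were lower in 8:2 FTS than in 8:2 FTOH (adjusted p = 3.12e-07, and adjusted p = 0.989 with an estimated correlation), 20 of 22 being negative and 5 falling over the list alone, with PIR, an iron-binding pirin, at -0.42 (-0.66 to -0.18) and ME1 at -0.31. In 8:2 FTS, mitochondrially encoded genes were higher by a median of 0.27 (adjusted p = 6.34e-08, and adjusted p = 0.989 with an estimated correlation), 13 of 13 positive. Both calls were kept with any 1 library left out, 8:2 FTOH replicate 3 included. Cholesterol genes were lower in 8:2 FTS at a median of -0.12 (adjusted p = 0.00287, and adjusted p = 0.989 with an estimated correlation), but not without 8:2 FTOH replicate 1 (0.242).

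8:2 FTS was also set against the perfluorinated sulfonates. Against PFOS, edgeR and DESeq2 called 0 genes (712 at an unadjusted p under 0.05 with edgeR; smallest adjusted p = 1). EGR1 differed by 0.23, FOS by 0.20, SLC7A11 by 0.05 and SQLE by -0.14 on the log2 scale. Cholesterol genes were lower in 8:2 FTS at a median of -0.15 (adjusted p = 1.48e-06), histone genes by -0.16 (1.25e-05) and retinoic acid response genes by -0.15 (1.13e-04), each kept with any 1 library left out and each at an adjusted p of 0.989 with an estimated correlation. MSMO1 differed by -0.27 (-0.47 to -0.07) and DHRS3, a retinaldehyde reductase gene, by -0.50. Against PFDS, edgeR called 0 genes (1020 at an unadjusted p under 0.05; smallest adjusted p = 0.249) and DESeq2 1. FOS differed by -1.52 (-2.14 to -0.91) and EGR1 by -0.27, neither past the threshold. Mitochondrially encoded genes were lower in 8:2 FTS than in PFDS at a median of -0.17 (adjusted p = 0.00126, and adjusted p = 0.989 with an estimated correlation), but not without PFDS replicate 1 (0.933) or 8:2 FTS replicate 2 (0.0947).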

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

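The counts over other splits of the libraries, the tests that leave out control libraries, the comparison of control handling and the NRF2 tests were chosen only after the results were seen. The tests of GC content, gene length and mitochondrial share were written before theirs.

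The effect of chain length differed between sulfonates and carboxylates for 5 lists, by a test of the difference itself, which is what singled them out; the adjusted p was 0.989 for each with an estimated correlation. Heat shock genes had a median difference of 0.16 on the log2 scale (adjusted p = 4.34e-05), kept with any 1 of the 12 libraries left out. The ATF4 list had -0.13 (4.81e-04), lost without PFDA replicate 3 (0.0657). ER chaperones had 0.08 (0.0067), lost without PFDS replicate 1 (0.0733), PFDS replicate 3 (0.118), PFOA replicate 2 (0.062) or PFOS replicate 1 (0.0969). Cell cycle genes had 0.10 (0.00353), lost without PFDS replicate 3 (0.39), PFOA replicate 2 (0.0566) or PFOS replicate 1 (0.296). Retinoic acid response genes had -0.13 (0.0351), lost without PFDA replicate 1 (0.0504), PFDA replicate 3 (0.0762), PFOA replicate 1 (0.151), PFOA replicate 3 (0.0535) or PFOS replicate 2 (0.156), and with the sign turned without PFDS replicate 1 (0.997).

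EGR1 and FOS were each lower than control for 5 compounds, 10 calls in all. A single control library as the cause is argued against: without control replicate 1, which had the highest EGR1 level (45.7 CPM), at least 79.21% of each log2 difference was left, and 8, 8 and 10 of the 10 calls were kept without control replicates 1, 2 and 3. A trend with the GC content of genes is argued against too, since 10 of 10 calls were left after it was removed. That the control cultures were handled differently from all treated cultures cannot be told apart from a response to the compounds, because every compound is compared with the same 3 controls; EGR1 passed in 0 comparisons between compounds and FOS in 1 (PFDS against PFOS). That FOS call was lost under library size scaling, in a fit of only the groups compared, and without PFDS replicate 1, PFDS replicate 2, PFOS replicate 1 or PFOS replicate 2, and 2 of 10 splits called as many genes, so it decides nothing here.

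More genes passed when control replicate 3 was left out, for 6 of 6 compounds, and for none when control replicate 1 or 2 was left out. That control replicate 3 alone widens the spread between controls restates this observation and stays open: its mean distance to the other controls was 80.3 (on log2 CPM), against 77.7 and 74.1 for control replicates 1 and 2. Relative to counting noise it stood further apart, with a chi-square per degree of freedom of 31.69 and 31.55 in its pairs with control replicates 1 and 2 against 7.939 between these, a measure that sets single libraries against technical noise and so does not decide. A distance over 1.5 times that of both was asked for, a limit set after these distances were seen. For PFOA the count rose from 8 to 139, and 8 genes passed with mitochondrially encoded genes removed before scaling. That removal leaves the counts of other genes as they are. It cannot decide whether the mitochondrial share of control replicate 3 (6.33%) marks a difference that also touches those genes. With a trend with GC content removed from all libraries 8 genes passed for PFOA, and 7 with a trend with gene length removed. Such trends are argued against only as what keeps the count low with all libraries. The fit without control replicate 3 was not repeated after removal, so a contrast in GC content there stays open. Deviations from the mean over libraries correlated with GC content at -0.25 (Spearman) in control replicate 3. The value was 0.16 and 0.10 in control replicates 1 and 2, and -0.15, -0.22 and -0.11 in PFOA replicates 1, 2 and 3. What sets control replicate 3 apart stays open, and no biological explanation was tested.

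The ATF4 list was higher than other genes for 5 compounds. A trend with GC content is argued against (5 of 5 calls left), and so is 1 control library, with 4 of 5 calls left without control replicate 1 and 5 of 5 without control replicate 2 or 3. NRF2 activity in place of ATF4 was not decided for PFOS and 8:2 FTS. There the ATF4 list without SLC7A11 passed with the preset correlation (adjusted p = 2.05e-20 and 1.06e-15, medians 0.25 and 0.26). The NRF2 list without SLC7A11 did not (lowest adjusted p = 0.1265, medians 0.06 and -0.01). The full NRF2 list had not passed for these compounds either, so the outcome without SLC7A11 was all but fixed. The values show only that the rise of the ATF4 list did not rest on SLC7A11 alone. For 8:2 FTOH both lists passed without SLC7A11 (NRF2 0.005323, ATF4 4.96e-14), so NRF2 and ATF4 cannot be told apart there either. With an estimated correlation, adjusted over the same 12 tests, the ATF4 list without SLC7A11 had 0.0388 for PFOS, 0.0494 for 8:2 FTS and 8:2 FTOH and 0.074 for PFDS, and the NRF2 list had 0.223 for 8:2 FTOH. Over the 192 tests of all lists, 0 passed with an estimated correlation. An amino acid stress response may be stated only as a hypothesis.

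With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count of genes and the highest of the other splits were 8 and 0 for PFOA (1 of 10 splits as large, the real one included), 6 and 0 for PFOS (1), 21 and 1 for 8:2 FTS (1), 8 and 2 for 8:2 FTOH (1), 2 and 8 for PFDA (2) and 6 and 15 for PFDS (4). In the last 2, a split other than the real one called more genes. A structure of the samples other than the groups could give this, but it was not tested. Between compounds, PFDS against PFOS had 1 and 2 (2 of 10 splits as large); PFDA against PFOA 0 and 0, PFOS against PFOA 0 and 0, PFDS against PFDA 0 and 5, 8:2 FTS against 8:2 FTOH 0 and 1, against PFOS 0 and 0 and against PFDS 0 and 3, with 10 of 10 splits as large where the real count is 0. For the interaction, 26 of 26 splits gave at least the real count of 0 and 1 of them called 401 genes. A structure of the samples was not tested there either.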

How the results depend on the processing

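Leaving out the 2 libraries absent from the authors' normalized table was chosen only after the results were seen. Counts of genes are given in the order PFOA, PFOS, PFDA, PFDS, 8:2 FTS, 8:2 FTOH against control, and were 8, 6, 2, 6, 21 and 8 as reported. Where a cause is not named, the cause was not tested.

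Without a filter on low counts they were 161, 52, 68, 86, 126 and 107, with 17 for PFDS against PFOS, 10 for PFDS against PFDA, 6 for 8:2 FTS against 8:2 FTOH, 2 for 8:2 FTS against PFOS, 1 for 8:2 FTS against PFDS and 1 for the interaction. The DESeq2 test gave 128, 19, 23, 34, 49 and 59, with 2 for PFDS against PFOS, 3 for 8:2 FTS against 8:2 FTOH and 1 for 8:2 FTS against PFDS. Its independent filtering left 75.63% of genes for PFOA and 95.01% for PFDA without an adjusted p, EGR1 and FOS among them, so those have no DESeq2 value. Fits of only the groups compared gave 93, 49, 65, 2, 52 and 29, with 6 for PFDS against PFOS, 2 for PFOS against PFOA, 1 for 8:2 FTS against 8:2 FTOH and 25 for 8:2 FTS against PFOS. Library size only gave 4 for PFOA, 13 for PFDS and 0 for PFDS against PFOS. A minimum fold of 2 gave 2 for PFOA, 1 for PFDS, 7 for 8:2 FTS and 2 for 8:2 FTOH, a stricter criterion by construction. Without the 2 libraries, counts were 174, 33, 24, 28 and 60 for PFOA to 8:2 FTS. Other counts stayed within 1.5 times the reported ones under these settings and with DESeq2 size factors and the stricter filter.

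Replicate numbers do not pair the libraries: residuals of 63 pairs with the same number correlated at a mean of -0.003, and 5 of 21 libraries correlated best with their own number. With a replicate block the PFDA count was 1, and no other count moved over 1.5 times.

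Leaving out 1 library at a time gave ranges of 1 to 139, 2 to 24, 1 to 21, 1 to 101, 3 to 44 and 1 to 32, with 0 to 3 for PFDS against PFOS and 0 to 1 for PFDS against PFDA. Fewer samples enter these fits.

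Of the list tests, 88 of 192 against control and 55 of 256 between compounds passed as reported, 74 to 91 and 45 to 66 with 1 library left out, 0 and 0 with an estimated correlation, and 0 and 0 with fry. Over all alternatives, 1659 of 2175 values of called list tests stayed on their side of the threshold, 503 were weaker and 13 turned their sign. The adjusted p of the turned tests ranged over left-out libraries from 5.02e-14 to 0.6788 (ribosomal proteins, PFDS), 9.28e-06 to 0.759 (retinoic acid, PFDS), 6.29e-12 to 0.8795 (histones, PFDS), 4.01e-12 to 0.6366 (ribosomal proteins, 8:2 FTOH, which were higher at 0.01844 without the 2 libraries), 1.14e-13 to 0.07184 (mitochondrially encoded, PFDA against PFOA), 6.68e-05 to 0.8655 (ribosomal proteins, PFDA against PFOA), and 1.98e-11 to 0.2366, 5.30e-09 to 0.9322, 3.35e-06 to 0.8872 and 1.80e-08 to 0.3379 (cholesterol, ribosomal proteins, retinoic acid and histones, PFDS against PFOS). For mitochondrially encoded genes in PFDS against PFDA it was 1.35e-31 to 0.988, and for retinoic acid in the interaction 1.28e-04 to 0.9967.

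Of 1877 values of named genes, 1492 stayed on their side of the threshold, 219 were weaker, 157 stronger and 9 turned their sign, all of the 9 for differences near 0 between compounds that had not passed. With 1 library left out these ranged from -0.07 to 0.10 for EGR1 and -0.03 to 0.08 for SQLE (PFDA against PFOA), from -0.13 to 0.02 for SLC7A11 (PFDS against PFDA), and from -0.04 to 0.50 for FOS and -0.04 to 0.11 for SLC7A11 (8:2 FTS against PFOS). The median covariance between compounds was 0.0668 and became 0.0365 with the stricter filter, which removes genes of low level.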

Other observations

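The comparison of the 6 compound groups together with control, its fits without each control library, its count over other splits and the same comparison for each other group were chosen only after the results were seen.

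With the 18 compound libraries set together against the 3 controls, 87 genes passed, 11 higher and 76 lower, 24 of them in a list. Lists were not tested in this comparison, so the genes below are single calls. Of genes for sterol synthesis, NSDHL fell by 0.40 on the log2 scale, ACAT2 by 0.33, SQLE by 0.29 and INSIG1 by 0.28. Of neurite genes, GAP43 fell by 0.34, DPYSL3 and MAP1B by 0.29 each and NEFM by 0.43. Of chaperone genes, HSPA8 fell by 0.32, HSP90AA1 by 0.27, DNAJA1 by 0.26 and PDIA3 by 0.30, and MANF by 0.47. MAOB fell by 0.52. EGR1 (-1.15, adjusted p = 1.38e-09) and FOS (-1.71, adjusted p = 4.91e-08) had the lowest adjusted p among the genes named here, and SLC7A11 (0.92, adjusted p = 8.93e-05), SLC7A5 (0.32) and VEGFA (0.29) were higher. For EGR1, FOS, SQLE, GAP43 and DPYSL3, 18 of 18 compound libraries lay below the lowest control, and for SLC7A11 18 of 18 lay above the highest, among genes selected for that difference.

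This result rests on 3 controls. Without control replicate 1, 5 genes passed and without control replicate 2, 3 did, all of them among the 87, while without control replicate 3 there were 156, with 64 shared. Of 40 splits of the libraries, 1, the real one, gave as many genes, and the highest of the others gave 12. These splits mix the groups, so they do not show whether any 1 of the groups differs as much from the other 6. With each group in turn set against the other 6, 1 of 7, control, gave 87, 8:2 FTOH gave 7 and the other 5 gave 0. With 7 groups, too few for a share under 0.05, this stays open. A difference in how the control cultures were handled has the same form as a shared effect of 6 compounds and may contribute.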
